A study of Homo sapiens with 8 samples.

How the data were processed

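RNA of BEAS-2B cells from 4 groups was sequenced and deposited as 8 tables, 1 per library, each with 26485 gene symbols in the same order and 1 value per gene. Neither the labels nor the table headers name the unit. The deposited values were read as FPKM (fragments per kilobase of transcript, scaled by sequenced fragments) from their properties: they are not whole numbers, each library has a different total, which neither TPM nor CPM would have, and low values show no whole-read steps. Reads were aligned with HISAT2 2.2.0 to hg38, per the submitters' processing notes; the program that made the values and its gene annotation are not given in the sources used here. Values of overlapping or read-through genes and of near-identical copies depend on how that program divided reads, and such genes are uncertain. An exact 0 can also be a failed estimate; 6408 genes were at 0 in all libraries, as was 1 of 39 proteasome subunit genes (PSMA8) and no RNA polymerase II subunit, initiation factor or complex I subunit gene. Whole reads could not be recovered, so the depth per library is unknown and no counting interval is given. No column of another series was present. No pair of libraries held identical values, and log2 values of library pairs correlated at r = 0.992 to 0.997 across genes, which are not independent replicates.

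Samples were grouped by the titles in the labels. Before the data were examined, the groups, the comparisons, the contrasts, the gene lists and the rule for named genes were fixed. That design assumed a table of counts and a count test. Because the values are FPKM, the tests were run instead on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, on genes with a mean of at least 1 FPKM over the libraries of the comparison. The pseudocount, the filter and the limma options were settled after the values, the calls under 4 combinations of pseudocount and filter, and the list results had been looked at. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Such a gene, if higher with LY96 siRNA under both PBS and HDM, can show an interaction above 0 at equal fold responses. Ratios named as fold are ratios of mean FPKM. The siRNA effect under HDM used the 6 HDM libraries. The HDM effect over both siRNAs, the HDM effect within each siRNA and the interaction (HDM response with LY96 siRNA minus that with control siRNA) were contrasts of one model with 4 group means over 8 libraries. Each fit had 4 residual degrees of freedom. The p-values are two-sided and Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05.

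The 20 gene lists cover epithelial cytokines and chemokines, NF-kB targets, TLR4 pathway components, interferon-stimulated, immediate-early, NRF2, unfolded protein and integrated stress response, cell cycle, extracellular matrix, matrix protease, sterol synthesis, hypoxia and glycolysis, epithelial junction, type 2 response, p53, leukocyte, fibroblast, endothelial, mitochondrially encoded and cytosolic ribosomal protein genes. Each list with at least 3 tested members was tested with camera at a preset correlation of 0.01, adjusted over 17 lists, and again with an estimated correlation and with the rotation test fry. Under the rule, the named genes were the 10 largest rises and 10 largest falls of the siRNA and the HDM comparison with a mean of at least 5 units whose groups did not overlap, the 5 largest interactions in each direction, up to 4 members of each list and a fixed set of receptor, cytokine and NF-kB genes. Not every gene chosen by this rule is reported here. The level of 5 had been set for CPM and was applied to FPKM. Coordinates are those of GENCODE v29 on GRCh38, which may differ from the annotation the authors used.

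The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold on the log2(FPKM + 1) scale. Simulated PBS libraries were given the same spread as simulated HDM libraries. The trial thus does not check whether real PBS libraries vary as HDM libraries do. At 2-fold, 97% of changed genes were recovered for the siRNA effect among 12598 genes, 97% for the HDM effect over both siRNAs, 90% and 97% for the HDM effect with control and LY96 siRNA, and 81% for the interaction, each of these 4 among 12604 genes. False calls were 16 of 213, 10 of 206, 13 of 202, 9 of 203 and 6 of 186 in the same order, so false calls were more than 0.05 of all calls for the siRNA effect and for HDM with control siRNA. Camera called 50 of 50 simulated lists of 20 genes shifted by log2 0.5 and 0 unshifted ones. The simulated lists were not given the correlation between genes seen in the real lists. That correlation was estimated at 0.646 for interferon-stimulated, 0.315 for cytokine and chemokine and 0.266 for stress response genes. The trial therefore cannot show how often camera at the preset correlation makes false calls in such lists. The alternatives tried were no low-value filter, a 2-fold minimum, a replicate block, other sets of libraries and an additive model, and leaving out each HDM library. Pseudocounts of 0.1 and 0.25, median-ratio scaling, quantile normalization and limma without trend or robust moderation were added after the data were seen. Figures were drawn with matplotlib 3.10.9.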

Results

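RNA sequencing was used to ask how BEAS-2B cells responded to house dust mite (HDM) extract with and without siRNA against LY96. BEAS-2B is a virus-immortalised human bronchial epithelial cell line, and HDM extract is an airborne allergen mixture. LY96 encodes MD-2, the protein that binds lipopolysaccharide together with the receptor TLR4. Cells received control or LY96 siRNA, were moved to BEBM medium, were given PBS or HDM extract 24 h after that, and were harvested a further 24 h later. There were 3 HDM libraries with control siRNA, 3 HDM libraries with LY96 siRNA and 1 PBS library with each siRNA. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The tables hold 26485 genes, and their FPKM totals ranged from 329777 to 340328. Read depth is unknown.

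LY96 (chromosome 8, 73991352 to 74029087, GRCh38) was listed at 0 FPKM in all 8 libraries, those with control siRNA included. Neither the expression of LY96 in these cells nor its depletion could therefore be checked from these values. Every LY96 siRNA group below is named by its label. TLR4, the partner receptor of MD-2, was at 4.55 FPKM with control siRNA and PBS, 3.99 ± 0.178 (SD, n = 3) with control siRNA and HDM, 5.80 with LY96 siRNA and PBS, and 4.34 ± 0.473 (SD, n = 3) with LY96 siRNA and HDM. CD14, the co-receptor that hands lipopolysaccharide to MD-2, was at 5.004 ± 0.348 FPKM with control siRNA and HDM and 4.71 ± 0.430 with LY96 siRNA and HDM (SD, n = 3 each). Ribosomal RNA (RNA18S5 plus RNA28S5) took 0.824%, 0.475% and 0.565% of the FPKM total in the control siRNA HDM libraries. It took 1.03%, 1.03% and 1.31% in the LY96 siRNA HDM libraries, and 0.770% and 0.826% in the control and LY96 siRNA PBS libraries.

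HDM extract raised neutrophil- and monocyte-attracting chemokine genes, averaged over both siRNAs. The largest rises and falls here are those of genes with a mean of at least 5 FPKM whose HDM libraries all lay on the same side of the PBS library of their siRNA. CXCL1 (chromosome 4, 73869393 to 73871242) went from 1.56 FPKM with PBS to 25.6 ± 1.15 (SD, n = 3) with HDM under control siRNA, and from 2.01 to 58.6 ± 11.2 (SD, n = 3) under LY96 siRNA (log2 3.83 ± 0.13 SE, adjusted p = 3.36e-05). CXCL8 (chromosome 4, 73740506 to 73743716), the gene for interleukin-8, went from 0.590 to 7.53 ± 0.276 FPKM and from 0.607 to 18.8 ± 2.51 (SD, n = 3 each, log2 3.02 ± 0.09 SE, adjusted p = 3.72e-07). CCL2 (chromosome 17, 34255218 to 34257203), a monocyte chemokine, rose 6.32-fold and 7.22-fold under control and LY96 siRNA (log2 2.66 ± 0.06 SE, adjusted p = 1.11e-07). The other genes among the 10 largest rises were CXCL2 (log2 2.69), the acute-phase genes SAA2 (2.59) and SAA1 (2.49), IL32 (2.43), the complement genes CFB (2.19) and C3 (2.16), and CHAC1 (2.09), a glutathione-degrading enzyme induced by ATF4. The largest falls included TAGLN (log2 -1.07 ± 0.12 SE), an actin-binding smooth muscle protein gene, APCDD1 (-1.04), a Wnt inhibitor, ANKRD1 (-0.96), LBH (-0.80), IGFBP3 (-0.76), the glucose transporter gene SLC2A3 (-0.75) and CYP4B1 (-0.73). TNNT2, S100P and SCEL were also among the 10 largest falls, but lost the call when single libraries were left out. TNNT2 (log2 -0.78) had adjusted p = 0.0695 and 0.0555 without control HDM replicate 2 and 3, and 0.0733 and 0.0529 without LY96 HDM replicate 1 and 2. S100P (-0.76) had 0.0553, 0.0669 and 0.0568 without control HDM replicate 1, 2 and 3, and 0.0636 without LY96 HDM replicate 1. SCEL (-0.73) had 0.0960 and 0.0890 without control HDM replicate 2 and 3, 0.0777 without LY96 HDM replicate 1, 0.0553 and 0.0526 with pseudocounts of 0.1 and 0.25, and 0.0654 without the low-value filter.

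Among 14 tested epithelial cytokine and chemokine genes, 13 rose and 0 fell with HDM (13 up and 0 down adjusted over the list alone), with a median log2 difference of 1.78. IL6 rose by log2 1.38 ± 0.12 SE, CSF1 by 1.00 ± 0.05, and CCL20, a dendritic cell chemokine, by 1.97 ± 0.09. CCL20 was listed at 0 in the control PBS library and reached 1.68 ± 0.223 FPKM with control siRNA and 5.58 ± 0.562 with LY96 siRNA under HDM (SD, n = 3 each). The epithelial alarmin genes TSLP and IL33 and the colony-stimulating factor genes CSF2 and CSF3 were below the level tested, and IL33 was listed at 0 in all 8 libraries. The list stood above other genes by limma's camera test (adjusted p = 1.13e-21, adjusted p = 0.0843 with an estimated correlation). All 16 tested NF-kB targets and feedback regulators rose (16 up and 0 down adjusted over the list alone, median log2 1.05, camera adjusted p = 1.26e-33, adjusted p = 0.0380 with an estimated correlation). TNFAIP2 rose by log2 2.01, the mitochondrial superoxide dismutase gene SOD2 by 1.65, the NF-kB inhibitor gene NFKBIA by 1.35, the adhesion molecule gene ICAM1 by 1.13 and TNFAIP3, which encodes the feedback enzyme A20, by 1.10.

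**Figure D1:**
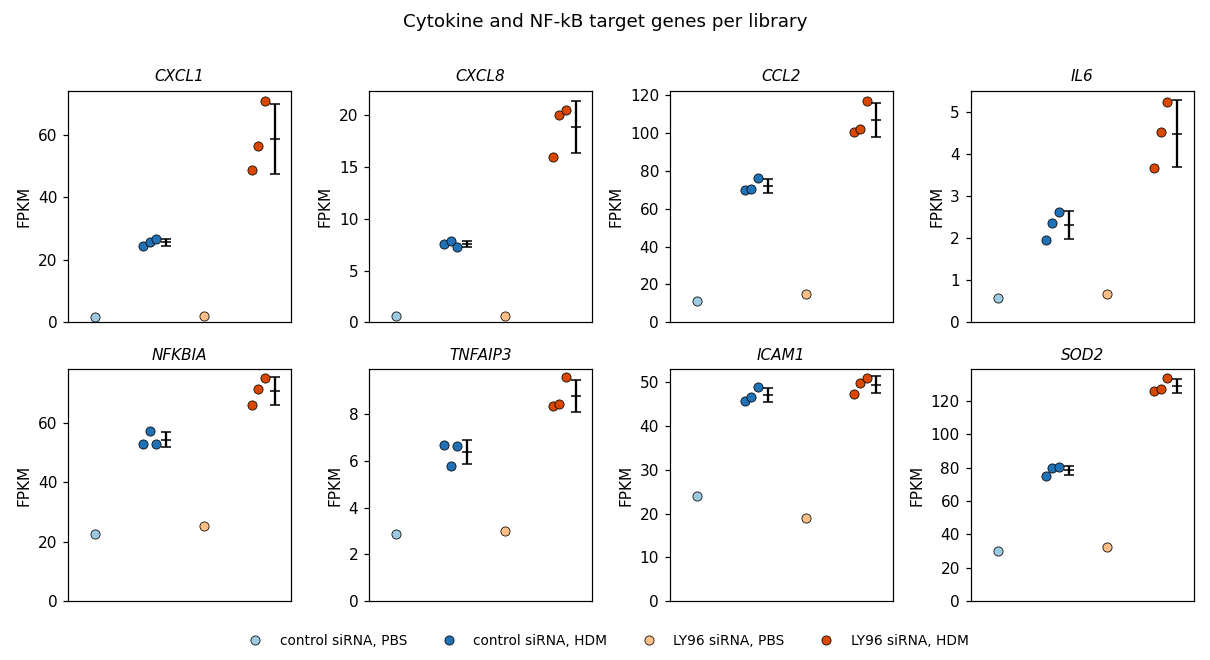
FPKM per library of 8 cytokine and NF-kB target genes in the 4 groups; each point is 1 library, and bars give the mean and SD of the 3 HDM libraries of a siRNA. CXCL8 lay at 0.590 and 0.607 FPKM with PBS, at 7.53 ± 0.276 with control siRNA and HDM, and at 18.8 ± 2.51 with LY96 siRNA and HDM.

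Stress-response genes rose with HDM over both siRNAs, with 16 of 20 unfolded protein and integrated stress response genes up and 0 down (18 up and 0 down adjusted over the list alone, median log2 0.43, camera adjusted p = 6.17e-17, adjusted p = 0.0971 with an estimated correlation). The median HDM response of this list was log2 0.18 with control siRNA and 0.70 with LY96 siRNA. In an additive model over all 8 libraries, ATF4, DDIT3 and PSAT1 lost the HDM call (adjusted p = 0.134, 0.216 and 0.138). Of the immediate-early and MAPK/EGFR response genes 10 of 24 rose and 2 fell (13 up and 3 down adjusted over the list alone, camera adjusted p = 7.48e-05, adjusted p = 0.264 with an estimated correlation). EGR1 (log2 0.57), JUNB (0.56) and AREG (0.56), a ligand of the EGF receptor, rose, and the phosphatase gene DUSP1 fell by 0.47. Among 20 extracellular matrix and TGF-beta response genes 4 rose and 8 fell (5 up and 11 down adjusted over the list alone, camera adjusted p = 0.00194, adjusted p = 0.0971 with an estimated correlation). TGFBI changed by log2 -0.49 and THBS1, a matrix glycoprotein gene, by -0.38, while the collagen cross-linking enzyme gene LOX rose by 0.33. Of 11 matrix protease and plasminogen genes 1 rose and 3 fell, TIMP3 among them at log2 -0.68 (1 up and 4 down adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.132 with an estimated correlation). Sterol synthesis genes had 5 of 21 up and 0 down, including HMGCS1 (log2 0.32) and DHCR7 (0.22) (10 up and 0 down adjusted over the list alone, camera adjusted p = 4.44e-05, adjusted p = 0.353 with an estimated correlation). Among 16 epithelial junction and airway markers 4 rose, among them MUC1 (log2 0.67) and TP63 (0.38), and 5 fell, among them KRT7 (-0.38) (5 up and 10 down adjusted over the list alone, camera adjusted p = 0.0357, adjusted p = 0.393 with an estimated correlation). The camera call of this list was lost after quantile normalization (adjusted p = 0.0647) and without the low-value filter (adjusted p = 0.0545).

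Cell cycle genes had 0 of 29 up and 1 down, the latter CDK1 (log2 -0.21), with 0 up and 1 down adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.132 with an estimated correlation). For p53 targets 4 of 17 rose and 1 fell (4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.353 with an estimated correlation). Cytosolic ribosomal protein genes had a median log2 difference of -0.04, with 0 of 83 up and 3 down (0 up and 0 down adjusted over the list alone, camera adjusted p = 6.04e-08, adjusted p = 0.353 with an estimated correlation). Interferon-stimulated genes had 2 of 34 up, BST2 (log2 0.20) and CXCL10 (0.94), and 0 down (2 up and 0 down adjusted over the list alone). TLR4 pathway components had 3 of 20 up, namely TLR2 (log2 0.64), TRAF3 (0.42) and CD14 (0.38), and 0 down (3 up and 1 down adjusted over the list alone). NRF2 target genes had 2 of 16 up and 2 down (2 up and 4 down adjusted over the list alone), and hypoxia and glycolysis genes 5 of 16 up and 2 down (6 up and 2 down adjusted over the list alone). Of the 3 tested type 2 epithelial response genes SERPINB4 (log2 0.86) and SERPINB3 (0.56) rose and SERPINB2 (-0.49) fell, the same calls as those adjusted over the list alone. SERPINB3 had adjusted p = 0.157 in an additive model, and SERPINB2 had adjusted p = 0.0506 without the low-value filter. Camera did not call these last 5 lists (adjusted p from 0.0987 for hypoxia and glycolysis to 0.228 for interferon-stimulated genes). The leukocyte markers CD74 (log2 0.71) and CD68 (0.40) rose, both also adjusted over the list alone, and CD68 had adjusted p = 0.0501 without the low-value filter. Of 3 tested fibroblast markers 0 rose and 1 fell, PDGFRB (log2 -0.60), with 1 up and 2 down adjusted over the list alone (camera adjusted p = 0.0987). No endothelial marker reached the level tested, and mitochondrially encoded genes were not analysed here.

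In all, 613 genes rose and 441 fell of 12604 tested at an adjusted p below 0.05 in limma (Benjamini-Hochberg), and 53 and 2 of them changed at least 2-fold. The excess of rises depended on scaling, with 555 up and 527 down after median-ratio scaling and 532 up and 532 down after quantile normalization. Each siRNA had a single PBS library, so the test assumes that it varies as the HDM libraries do. Tested within control siRNA, HDM raised 195 genes and lowered 93, and within LY96 siRNA it raised 367 and lowered 250. Both tests called 147 rises and 69 falls in common, where independent lists would share 5.68 and 1.84. The 2 differences share no library, but both tests take each gene's variance from the same 6 HDM libraries. Their calls are therefore coupled, and independent lists are no fair reference. By sign alone, 189 of the 195 rises and 90 of the 93 falls with control siRNA went the same way with LY96 siRNA. The control siRNA count of 288 fell to 187 without control HDM replicate 2.

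With LY96 siRNA under HDM, 16 of 20 stress response, 12 of 14 cytokine and chemokine and 12 of 16 NF-kB target genes rose, and 19 of 34 interferon-stimulated genes fell. As lists these did not pass camera with an estimated correlation (adjusted p = 0.151, 0.156, 0.151 and 0.436 with an estimated correlation). The comparison sets the 3 LY96 siRNA HDM libraries against the 3 control siRNA HDM libraries. CHAC1 was at 2.26 ± 0.606 FPKM with control siRNA and 19.3 ± 2.65 with LY96 siRNA (SD, n = 3 each, log2 2.64 ± 0.15 SE, adjusted p = 2.56e-04). PSAT1 (chromosome 9, 78297143 to 78330093), a serine synthesis enzyme gene, was at 13.8 ± 0.852 and 56.5 ± 8.48 FPKM (SD, n = 3 each, log2 1.95 ± 0.10 SE, adjusted p = 2.14e-04). Among genes with a mean of at least 5 FPKM whose siRNA groups did not overlap, the 10 largest rises began with these 2. ASNS, the asparagine synthetase gene, rose 4.11-fold (log2 1.92 ± 0.13 SE), followed by STC2 (1.55), DDIT4 (1.49), NUPR1 (1.39), TRIB3 (1.25), CXCL8 (1.21), CXCL1 (1.15) and DDIT3 (1.14), which encodes the stress transcription factor CHOP. In an additive model over all 8 libraries, ASNS had adjusted p = 0.0504 and DDIT3 0.101. IFI27 (chromosome 14, 94104836 to 94116698), an interferon-stimulated gene, fell from 266 ± 37.7 to 80.7 ± 1.77 FPKM (SD, n = 3 each, log2 -1.70 ± 0.10 SE, adjusted p = 5.33e-04). FEN1 (chromosome 11, 61792637 to 61797244), the flap endonuclease gene of DNA replication, fell from 69.1 ± 0.997 to 33.5 ± 1.60 FPKM (SD, n = 3 each, log2 -1.03 ± 0.04 SE, adjusted p = 1.29e-05), the smallest p of any gene that fell.

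The other 8 of the 10 largest falls, by the same level and overlap limits, were KRTDAP (log2 -1.49 ± 0.12 SE), the cornified envelope precursor genes SPRR1A (-1.36 ± 0.21) and SPRR2E (-1.17 ± 0.15), the protease inhibitor gene SPINK5 (-1.23), the skin protease gene KLK7 (-1.18), SBSN (-1.02), SCEL (-0.95) and the chloride channel gene CLIC3 (-1.02). SPRR genes are near-identical copies in part, so reads may be split between them. SPRR1A had adjusted p = 0.0151, and 0.0604 without control HDM replicate 2. SBSN had 0.0165, and 0.0509, 0.0585 and 0.0571 without control HDM replicate 1, control HDM replicate 3 and LY96 HDM replicate 2. KRT19 (log2 -0.66), KRT8 (-0.25) and KRT18 (-0.24), keratins of simple epithelia, were among 6 of 16 epithelial junction and airway markers that fell, while the E-cadherin gene CDH1 (log2 0.49) was among 2 that rose (3 up and 8 down adjusted over the list alone). The call of that list (camera adjusted p = 0.0457, adjusted p = 0.455 with an estimated correlation) was lost without control HDM replicate 1 (adjusted p = 0.116) and without LY96 HDM replicate 3 (adjusted p = 0.123). Camera also did not call it without the low-value filter (adjusted p = 0.0736) or in an additive model over all 8 libraries (adjusted p = 0.218).

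**Figure D2:**
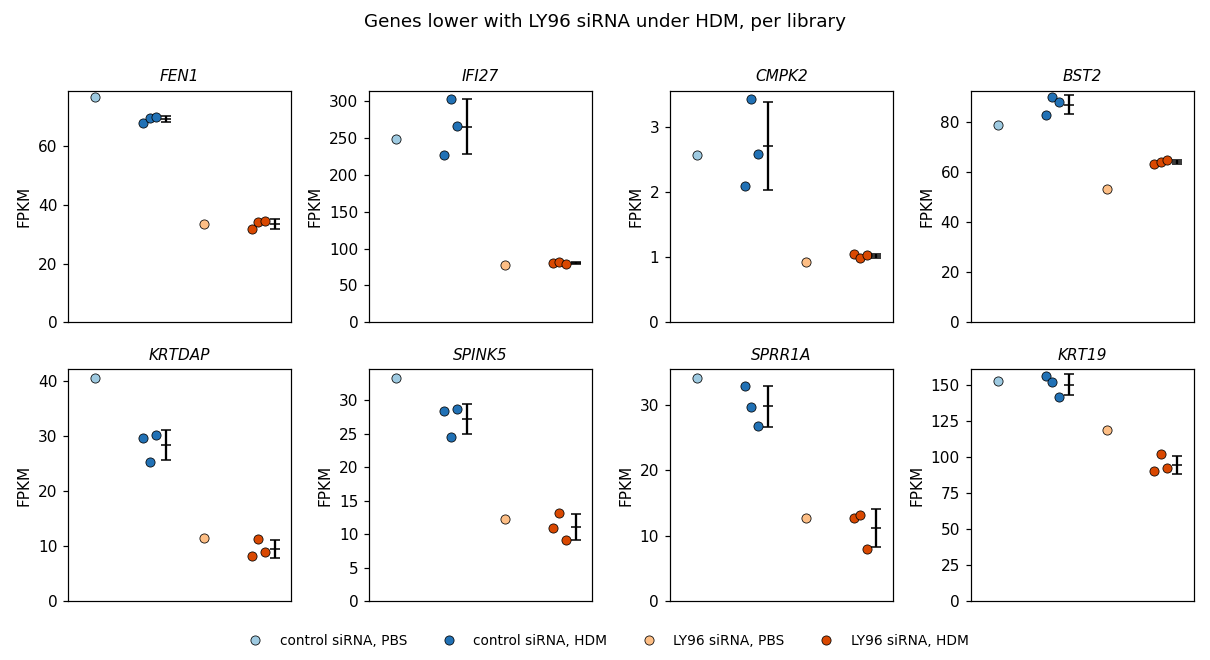
FPKM per library of 8 genes that were lower with LY96 siRNA under HDM; each point is 1 library, and bars give the mean and SD of the 3 HDM libraries of a siRNA. FEN1 lay at 76.6 FPKM with control siRNA and 33.4 with LY96 siRNA under PBS, and at 69.1 ± 0.997 and 33.5 ± 1.60 under HDM.

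Of 20 unfolded protein and integrated stress response genes 16 rose and 0 fell (16 up and 0 down adjusted over the list alone, median log2 0.73, camera adjusted p = 3.75e-17, adjusted p = 0.151 with an estimated correlation). ATF4 (log2 0.93 ± 0.05 SE), the transcription factor of the integrated stress response, HERPUD1 (0.82) and the serine synthesis gene PHGDH (0.77) were among those that rose. Of 14 cytokine and chemokine genes 12 rose and 0 fell (13 up and 0 down adjusted over the list alone, median log2 0.69, camera adjusted p = 3.79e-12, adjusted p = 0.156 with an estimated correlation), with CCL20 at log2 1.29, CXCL6 at 1.09, IL6 at 0.72 and CCL2 at 0.56. Of 16 NF-kB targets 12 rose and 0 fell (14 up and 0 down adjusted over the list alone, median log2 0.31, camera adjusted p = 1.31e-12, adjusted p = 0.151 with an estimated correlation), among them SOD2 (0.71), TNFAIP2 (0.67), RELB (0.45), TNFAIP3 (0.41) and NFKBIA (0.37); ICAM1 was at log2 0.07 (adjusted p = 0.277). Of 34 interferon-stimulated genes 0 rose and 19 fell (1 up and 25 down adjusted over the list alone, median log2 -0.29, camera adjusted p = 3.90e-10, adjusted p = 0.436 with an estimated correlation), among them CMPK2 (log2 -0.86), BST2 (-0.43) and STAT2 (-0.25). Cytosolic ribosomal protein genes had 12 of 83 up and 5 down (16 up and 6 down adjusted over the list alone, median log2 0.05, camera adjusted p = 1.55e-04, adjusted p = 0.455 with an estimated correlation), and the camera call was also lost after quantile normalization (adjusted p = 0.211). The share of ribosomal RNA was higher in each LY96 siRNA HDM library than in each control siRNA HDM library, alongside all of these groups.

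Camera did not call the other lists for LY96 siRNA under HDM (adjusted p from 0.0703 to 0.693). Immediate-early genes had 7 of 24 up, among them JUNB (log2 0.56) and EGR1 (0.45), and 1 down (7 up and 3 down adjusted over the list alone). NRF2 target genes had 4 of 16 up, among them the cystine transporter gene SLC7A11 (log2 1.81 ± 0.08 SE) and HMOX1 (0.38), and 2 down, among them TXNRD1 (-0.35) (6 up and 3 down adjusted over the list alone). Sterol synthesis genes had 6 of 21 up, including INSIG1 (log2 0.44), and 1 down, MSMO1 (-0.23) (6 up and 1 down adjusted over the list alone). Extracellular matrix genes had 5 of 20 up, including COL5A1 (log2 0.44) and SPARC (0.29), and 3 down, including TAGLN (-0.81) and THBS1 (-0.33) (6 up and 4 down adjusted over the list alone). Matrix protease genes had 1 of 11 up, PLAU (log2 0.22), and 4 down, including MMP2 (-0.57) (2 up and 4 down adjusted over the list alone). Cell cycle genes had 4 of 29 up and 2 down (5 up and 3 down adjusted over the list alone), p53 targets 3 of 17 up and 4 down (3 up and 5 down adjusted over the list alone), and hypoxia and glycolysis genes 1 of 16 up, VEGFA (log2 0.49), and 3 down (1 up and 5 down adjusted over the list alone). VEGFA had adjusted p = 0.0717 in an additive model over all 8 libraries. Among 20 TLR4 pathway components only TLR2 rose (log2 0.36, adjusted p = 0.0155, 1 up and 0 down adjusted over the list alone), and it had adjusted p = 0.0508 and 0.0506 without control and LY96 HDM replicate 3. Of 3 type 2 response genes SERPINB2 fell (log2 -0.62, 0 up and 1 down adjusted over the list alone). Of the markers of other cells, CD68 rose (log2 0.54, 1 up and 0 down adjusted over the list alone among 2 leukocyte markers), and THY1 (log2 0.42) and COL1A1 (0.37) rose among 3 fibroblast markers (2 up and 0 down adjusted over the list alone). COL1A1 had adjusted p = 0.0658, 0.0684 and 0.0834 without control HDM replicate 1, 2 and 3, 0.0724 without the low-value filter, and 0.0515 in limma without trend or robust moderation.

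In all, 842 genes were higher and 1124 lower with LY96 siRNA under HDM of 12598 tested in limma, of which 16 and 15 differed at least 2-fold. The total of 1966 fell to 1119 without control HDM replicate 2 and 1243 without control HDM replicate 3. Higher genes made up 42.8% of the calls on FPKM as deposited and 54.3% (1061 up, 894 down) after median-ratio scaling. They made up 50.8% after quantile normalization.

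The PBS libraries compared the siRNAs without HDM, 1 library against 1. The difference has no replicate check and was not tested. IFI27 was at 249 FPKM with control siRNA and 77.3 with LY96 siRNA, FEN1 at 76.6 and 33.4, KRTDAP at 40.4 and 11.4, and SPINK5 at 33.4 and 12.3. ATF4 was at 123 and 135 FPKM, ASNS at 7.96 and 8.39, and CXCL8 at 0.590 and 0.607. Interferon-stimulated genes had a median log2 difference of -0.20 (LY96 minus control siRNA), with 32 of 34 below 0. The stress response list had a median of 0.07 (13 of 20 above 0), the cytokine list 0.09 (11 of 14 above 0) and the NF-kB list 0.08 (12 of 16 above 0). Of 1965 genes called for siRNA under HDM that differed between the PBS libraries, 1752 (89.2%) differed in the same direction there.

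The HDM response was larger with LY96 siRNA for 7 genes, the interaction calls in limma. DDIT3 changed by log2 0.12 with control siRNA and 1.51 with LY96 siRNA (difference 1.39 ± 0.15 SE, adjusted p = 0.0430). SLC7A11 (chromosome 4, 138164097 to 138242349) changed by 0.17 and 1.93 (difference 1.76 ± 0.17, adjusted p = 0.0384), ATF4 (chromosome 22, 39519695 to 39522685) by 0.17 and 0.97, and SOD2 (chromosome 6, 159669057 to 159745186) by 1.34 and 1.95. The mitochondrial folate enzyme gene MTHFD2, STC2 and the long pentraxin gene PTX3 were the others. PTX3 lay under the level set for named genes and was named after its values were seen. The count was 0, 5 (2 of them smaller responses with LY96 siRNA) and 3 (1 smaller) without control HDM replicate 1, 2 and 3. It was 2, 33 (2 smaller) and 4 without LY96 HDM replicate 1, 2 and 3. It was 0 in limma without a variance trend or robust moderation, where 967 genes had an unadjusted p below 0.05, against 956 in the main test. CXCL8 (difference log2 1.19 ± 0.18 SE, adjusted p = 0.0889), CCL20 (1.11 ± 0.19, adjusted p = 0.107) and CXCL1 (0.92 ± 0.26, adjusted p = 0.516) did not pass.

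**Figure D3:**
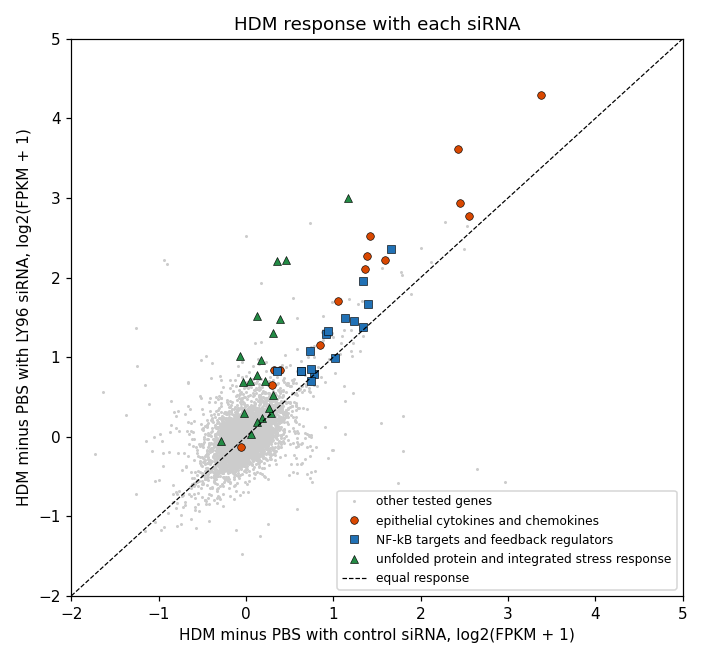
HDM minus PBS difference in log2(FPKM + 1) with control siRNA (horizontal) against LY96 siRNA (vertical) for all tested genes, with 3 fixed gene lists marked and a dashed line of equal response; 6 genes lie outside the axes. The median stress response gene differed by 0.18 with control siRNA and 0.70 with LY96 siRNA.

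As lists, stress response genes had 19 of 20 interaction values above 0 (median log2 0.64, 2 called over all genes, 12 up and 0 down adjusted over the list alone, camera adjusted p = 1.02e-19, adjusted p = 0.136 with an estimated correlation). Cytokine and chemokine genes had 13 of 14 above 0 (median 0.57, 0 called over all genes, 11 up and 0 down adjusted over the list alone, camera adjusted p = 6.28e-11, adjusted p = 0.136 with an estimated correlation). Several of these genes were low with PBS, where the log2(FPKM + 1) scale can give an interaction at near-equal fold responses. CXCL2 rose 16.3-fold and 17.2-fold with HDM under control and LY96 siRNA, whereas CXCL8 rose 12.8-fold and 31.0-fold. The median is therefore not a difference in fold response. NF-kB targets had 14 of 16 above 0 (median 0.24, 1 called over all genes, 7 up and 0 down adjusted over the list alone, camera adjusted p = 2.18e-09, adjusted p = 0.136 with an estimated correlation). Epithelial junction and airway markers leaned the other way, with 2 of 16 above 0 (median -0.28, 0 called over all genes, 0 up and 4 down adjusted over the list alone, camera adjusted p = 9.60e-07, adjusted p = 0.217 with an estimated correlation), as did matrix protease genes (median -0.19, camera adjusted p = 0.00458, adjusted p = 0.136 with an estimated correlation). Immediate-early genes (median 0.10, camera adjusted p = 0.00378, adjusted p = 0.407 with an estimated correlation) and ribosomal protein genes (median 0.07, camera adjusted p = 9.37e-07, adjusted p = 0.418 with an estimated correlation) leaned up with no gene called. The call of the ribosomal protein list was lost after quantile normalization (median 0.02, camera adjusted p = 0.361). The other lists were not called by camera (adjusted p from 0.0517 to 0.999), and SLC7A11 was their single interaction call over all genes.

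**Figure D4:**
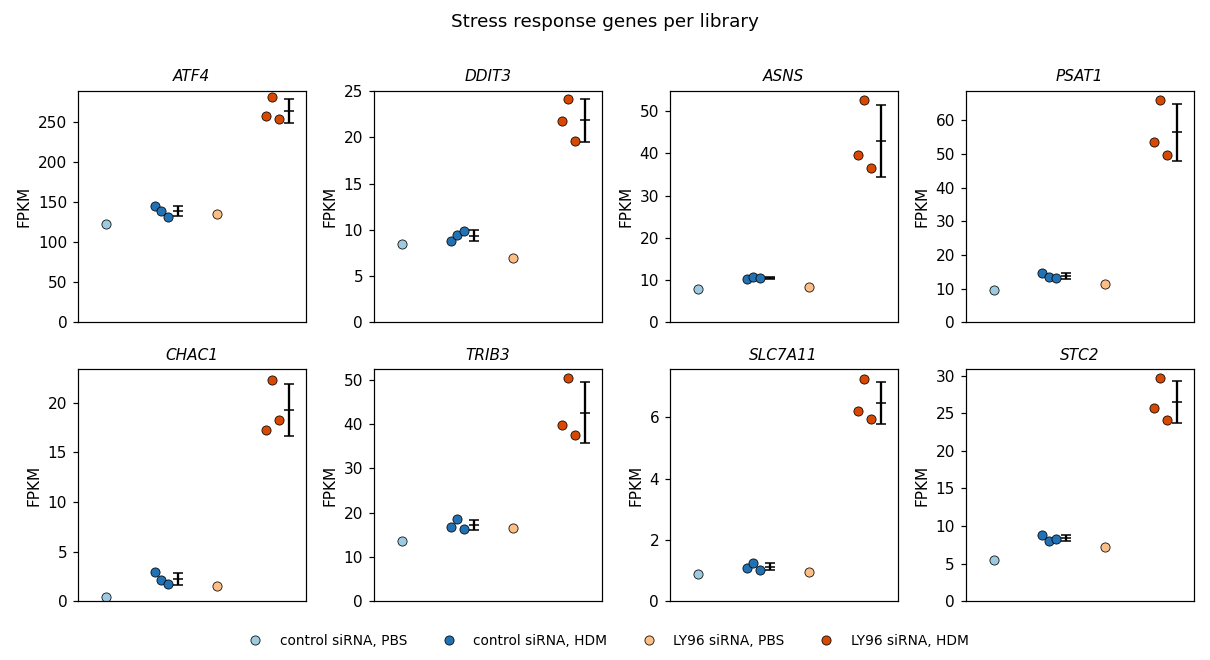
FPKM per library of 8 stress response genes in the 4 groups; each point is 1 library, and bars give the mean and SD of the 3 HDM libraries of a siRNA. ATF4 lay at 123 and 135 FPKM with PBS, at 139 ± 6.34 with control siRNA and HDM, and at 264 ± 15.0 with LY96 siRNA and HDM.

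Genes that HDM raised were taken as a set to see whether LY96 siRNA moved them back toward PBS levels. The 613 raised genes had a median difference of log2 0.09 (LY96 minus control siRNA under HDM), with 228 higher and 40 lower with LY96 siRNA, where independent calls would give 41.0 and 54.7 (camera p = 1.08e-17, p = 0.0120 with an estimated correlation). Those raised at least 2-fold, 53 genes, had a median of log2 0.48, with 39 higher and 5 lower (p = 0.0194 with an estimated correlation). The median interaction of all 613 raised genes was log2 0.05 (p = 0.0571 with an estimated correlation). That of the 441 lowered genes was log2 -0.07 (p = 0.132 with an estimated correlation). Neither passed 0.05. The median interaction of the genes raised at least 2-fold was log2 0.37 (p = 0.0203 with an estimated correlation). The genes that HDM lowered had a median of log2 -0.08 with LY96 siRNA (camera p = 7.05e-05, p = 0.240 with an estimated correlation). Of these 436 genes 138 were called lower and 41 higher, where independent calls would give 38.9 and 29.1. The siRNA and HDM tests both take each gene's variance from the same 6 HDM libraries. These counts are therefore coupled, and independent calls are no fair reference for the raised or the lowered genes. The error of the average HDM effect is uncorrelated with that of both contrasts in this balanced set, so the choice of genes does not by itself push these medians one way.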

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

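The tests of explanations for the 3 patterns were chosen after the result was seen, while the interaction contrast and the regrouping of the 6 HDM libraries were set before. The HDM response differed between the siRNAs, by the interaction test in limma, for 7 genes. The response with LY96 siRNA minus that with control siRNA was log2 0.80 for ATF4, 1.39 for DDIT3, 1.01 for MTHFD2, 1.96 for PTX3, 1.76 for SLC7A11, 0.61 for SOD2 and 1.21 for STC2. Their adjusted p ranged from 0.0384 (SLC7A11) to 0.0467 (PTX3), and each response rests on 1 PBS library per siRNA. None of the 7 passed without control HDM replicate 1. For the siRNA effect under HDM, the real grouping gave 1966 genes and the highest of the other 9 of 10 splits of the 6 libraries gave 1; 10 splits are too few for a share under 0.05.

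The first pattern is that cytokine, chemokine and NF-kB genes were higher, not lower, with LY96 siRNA under HDM, in 12 of 14 cytokine and chemokine and 12 of 16 NF-kB genes called (median log2 0.42, camera adjusted p = 0.156 and 0.151 with an estimated correlation). Library scaling is argued against, since the median was log2 0.43 after quantile normalization. For ribosomal RNA carry-over, the slope within groups was 0.0704 log2 per log2 ribosomal RNA (95% interval -0.25 to 0.39), where 0.57 would be needed. That interval assumes a common slope and spread. The SD of the mean level was 0.00635 with control and 0.0849 with LY96 siRNA. The LY96 siRNA HDM libraries rose in the order of their ribosomal RNA (3.74, 3.82 and 3.91 in mean log2 level), so carry-over is not excluded. An exchange of the siRNA labels of the HDM libraries stays open: 89.2% of called genes had the same sign between the PBS libraries, but that is 1 library of each siRNA, and LY96 at 0 gives no check. A larger HDM response with LY96 siRNA is a hypothesis that goes with the interaction of these genes (p = 0.0256 with an estimated correlation), found and tested on the same libraries and resting on 1 PBS library per siRNA. Whether LY96 was expressed, and whether MD-2 was depleted, stays open.

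The second pattern is that 16 of 20 stress response genes were higher with LY96 siRNA under HDM (median log2 0.73, camera adjusted p = 0.151 with an estimated correlation). It stayed at log2 0.74 after quantile normalization, and the within-group slope on ribosomal RNA was -0.0176 (95% interval -0.43 to 0.40) where 0.91 would be needed. This interval too assumes a common slope, and ribosomal RNA did not overlap between the groups, so carry-over is not excluded. LY96 siRNA by itself stays open as a cause: the median between the PBS libraries was log2 0.0664, but 1 library of each siRNA excludes nothing. The median interaction of the list was log2 0.64, with 19 of 20 genes above 0 (camera p = 0.0140, adjusted p = 0.136 with an estimated correlation). That interaction rests on the same PBS libraries. The 3 LY96 siRNA HDM libraries all lay above the control siRNA HDM libraries, with a gap of log2 0.71 in the mean level of the list. A shared difference in handling of these dishes, such as medium or density, and a joint effect of LY96 siRNA and HDM cannot be told apart, because the labels give no batch.

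The third pattern is the fall of FEN1 with LY96 siRNA (log2 -1.03 under HDM). A slower cell cycle is argued against by the 29 tested cell cycle genes, whose median was log2 0.0310 and lowest value -0.26. A direct action of the LY96 siRNA on FEN1 messenger RNA is a possible explanation that stays open: the difference between the PBS libraries was log2 -1.17, as it would have to be, but the siRNA sequence is not given in the sources used here, nor whether a single siRNA or a pool was used. An effect of MD-2 loss on FEN1 predicts the same values and was not tested.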

How the results depend on the processing

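The alternative pseudocounts, median-ratio scaling, quantile normalization and limma options were chosen after the data were seen, as was the low-value filter of the test itself. The other alternatives were set before. DESeq2 and limma-voom need counts and were not run, and size factors were computed on FPKM instead (median-ratio scaling). No named gene and no list changed direction with a call under any setting run. Direction was not compared for the other genes. Leaving out each HDM library gave 1119 to 1369 genes for siRNA under HDM, 774 to 936 for HDM over both siRNAs, 187 to 329 and 493 to 593 for HDM with control and LY96 siRNA, and 0 to 33 for the interaction, with fewer libraries as the known difference. Of the named genes called, 68 of 80 (siRNA), 72 of 79 (HDM) and 0 of 6 (interaction) kept the call in all 6 of these fits. A 2-fold minimum left 31, 55, 41, 72 and 5 genes in the same order, by construction. The interaction count of 7, all larger responses with LY96 siRNA, became 20 without the low-value filter. Of these 20, 13 were larger and 7 smaller responses, with 1 of the main calls among them. The count was 11 with median-ratio scaling, 14 with quantile normalization and 0 in limma without trend or robust moderation. The last setting also gave 180 genes for HDM with control siRNA. The cause was not tested. Pseudocounts of 0.1 and 0.25 gave 1949 and 1960 genes for siRNA under HDM and 1057 and 1056 for HDM over both siRNAs. With an estimated correlation all 6 camera calls for siRNA, all 7 for the interaction and 10 of 11 for HDM were lost, NF-kB targets with HDM being the exception. The shift of HDM-lowered genes (median log2 -0.0776) was lost too (camera p = 0.240 with an estimated correlation). Fitting siRNA on all 8 libraries gave 1968 genes with 4 group means and 2482 in an additive model. Same-numbered HDM libraries deviated from their group means with correlations of 0.0485, -0.0165 and -0.0162, and not every library correlated best with its own number, so the numbers were not read as pairs. A replicate block gave 1635, 854, 212, 510 and 3 genes. There 4 of 6 named interaction calls were lost, ATF4 (adjusted p = 0.0690), DDIT3 (0.0849), SOD2 (0.0690) and STC2 (0.0929). Also lost were 7 of 79 named HDM calls, among them LBH (0.115), TNNT2 (0.103), S100P (0.0651) and SERPINB2 (0.0727), and 2 of 80 siRNA calls. In fry 5 of 7 interaction lists were lost, cytokines (adjusted p = 0.0594), NF-kB targets (0.0517), immediate-early (0.273), junction (0.131) and ribosomal protein genes (0.273). Ribosomal protein genes were lost for siRNA (0.140), and sterol (0.0585), junction (0.238) and ribosomal protein genes (0.0826) for HDM. Fry called 3 siRNA and 4 HDM lists that camera did not. Read depth is unknown, so low genes, LY96 among them, cannot be bounded.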

Other observations

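Both gene sets and their tests in this part were chosen after the data were seen. The epidermal differentiation complex is a cluster of genes for the cornified layer of skin on chromosome 1, taken here as the protein-coding genes from 151982915 to 153632039 (GRCh38), which span S100A10 to S100A1. Of 30 tested genes of the cluster 18 fell and 2 rose with LY96 siRNA under HDM, with a median log2 difference of -0.47, SPRR1A and SPRR2E among those that fell. Between the PBS libraries 23 of 30 were lower with LY96 siRNA, with a median of log2 -0.37. With HDM over both siRNAs 7 of 29 tested rose and 2 fell, with a median of log2 0.01. The hypothesis that the cluster as a group may be lower with LY96 siRNA under HDM had camera p = 2.67e-08, but p = 0.0808 with an estimated correlation of 0.221, so it stays open; the test also ran on a cluster noticed through genes that had fallen.

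Cytosolic aminoacyl-tRNA synthetase genes, which load amino acids onto transfer RNA and include known ATF4 targets, were taken by symbol as EPRS and the genes named by 1 letter before ARS. Of 18 tested, 14 rose and 0 fell with HDM over both siRNAs (median log2 0.19; p = 0.0498 with an estimated correlation), and 10 rose and 0 fell with LY96 siRNA under HDM (median 0.17; p = 0.103 with an estimated correlation). The hypothesis that their HDM response may be larger with LY96 siRNA, as for ATF4, gave a median interaction of log2 0.22 with 14 of 18 above 0 (camera p = 9.94e-11; p = 0.0571 with an estimated correlation), which did not pass 0.05.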
